A study of Homo sapiens with 32 samples.

How the data were processed

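Bulk RNA-seq of MCF7 cells with a doxycycline-inducible Y537S ER was deposited as 32 libraries in 6 groups. Y537S cells had doxycycline at 1 µg/ml and WT cells had none. Resistant cells grew in palbociclib at 1 µM or abemaciclib at 1 µM, and vehicle cells in 0.01% DMSO. RNA was extracted with TRIzol and RNeasy and libraries were made with the KAPA mRNA HyperPrep kit. The series also covers single-cell RNA-seq and chromatin accessibility, which were not analysed here. Titles carry 2 numbers after the group, whose meaning the labels do not give. Libraries with the same first number were summed into a unit, which gave 16 units: 3 each for WT vehicle, WT palbociclib-resistant, WT abemaciclib-resistant and Y537S vehicle, and 2 each for resistant Y537S cells. Whether units were separate cultures is not given, so p-values of single genes measure only the spread between these samples, which may be technical. Libraries of 1 unit correlated across genes at 0.9877 to 0.9935 and differed by more than counting noise. In WT vehicle cells libraries of different units were about as alike (0.991 to 0.9944) as those of 1 unit (0.9922 to 0.9933). In each resistant group libraries of different units were less alike than those of 1 unit. They correlated at 0.9727 to 0.9803 (WT palbociclib), 0.9825 to 0.991 (WT abemaciclib), 0.9869 to 0.9884 (Y537S palbociclib) and 0.9741 to 0.9749 (Y537S abemaciclib). All abemaciclib-resistant libraries were of batch 2 and all others of batch 1, per the labels.

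The submitters' processing notes name STAR 2.7.0f, Cufflinks, DESeq2 and the hg19 genome. Their roles, filters, strand setting, annotation and batch-correction method, and the handling of reads that match more than 1 gene, are not given in the sources used here. The deposited STAR table holds raw counts (a count per gene and library) of 20114 genes. A deposited Cufflinks table holds FPKM values of 20111 genes. In 2 further deposited tables the authors corrected the values for batch, which leaves a score and not a measured count or FPKM: 14000 genes from STAR and 17501 from Cufflinks. Library totals ran from 18867740 to 83909691 counts (18.9 M to 83.9 M) and unit totals from 42.4 M to 105 M. By group, libraries held 18.9 M to 43.1 M counts (WT vehicle), 19.4 M to 83.9 M (WT palbociclib), 20.6 M to 32.2 M (WT abemaciclib), 19.7 M to 68.2 M (Y537S vehicle), 23.9 M to 26.6 M (Y537S palbociclib) and 21.9 M to 26.8 M (Y537S abemaciclib). The mitochondrial share of counts ran from 6.85% to 20.9%, and both abemaciclib groups (10.8% to 12.7%) lay above both palbociclib groups (6.85% to 10.2%). The first and second principal components of the units held 38.6% and 21.8% of the variance.

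Summed counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, robust quasi-likelihood F tests), all 6 groups in a single fit. filterByExpr (minimum count 10, minimum total 15) kept 14173 genes. There were 9 comparisons: Y537S against WT in each of 3 states, palbociclib resistance against vehicle and abemaciclib against palbociclib resistance in each genotype, and the differences of those last responses between genotypes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called; tests were two-sided. The SE of a fold change is its absolute value over the square root of its F statistic. Intervals of fold changes are 1.96 SE to each side, nominally 95%. They use normal quantiles and the F tests do not, so they are somewhat too narrow. A gene with 3 or fewer counts in a group is given as a ratio with a 95% counting interval in place of its fitted fold change, and such intervals cover counting error only. Expected overlaps assume that calls in both comparisons are independent.

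Before the data were examined, 23 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The rule always names ESR1, CCND1, CDK4, CDK6, RB1, CCNE1, CCNE2, CDKN1A, GREB1, TFF1 and PGR. It adds the 6 highest and 6 lowest fold changes among called genes with a mean log2 CPM of at least 2 and groups that do not overlap (a condition dropped for the differences between responses), leaving out histone, antisense and symbols of uncharacterized or small non-coding RNA. Of each called list it adds up to 3 members with the smallest adjusted p. The text gives a part of the genes so named.

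Lists were tested with camera in limma 3.58.1, which asks whether a list's genes move against all others, with a preset correlation of 0.01 and adjustment over 207 tests. At that value camera's p-values treat genes as nearly independent, so they rest mainly on the spread between genes and not between units. Camera called 72 of 207. With an estimated correlation it called 0 (smallest adjusted p = 0.174; 15 tests at an unadjusted p under 0.05), so every list call rests on the preset value. Fry, which asks whether a list's genes move on balance in 1 direction, called 56, of which 45 were among the 72.

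Alternatives were DESeq2 1.42.0 (Wald test), limma voom, upper-quartile and DESeq2 size factors, no filter and a stricter one, single libraries as replicates, single libraries with an estimated correlation within units, the first number as a block, only the groups compared, leaving out each unit, and the 3 other deposited tables (limma on log2 of the value plus 1, or 0.1 for Cufflinks). For those tables the tested genes were kept and libraries of a unit were averaged. The batch-corrected STAR values were then scaled to the same sum in each unit before the log. Negative values in either batch-corrected table were taken as no expression. Data of 14173 genes were simulated with 1 spread per gene shared by all groups and 66 or 67 genes changed at each fold. On them edgeR recovered 26.9%, 71.6% and 95.5% of genes changed 1.5-, 2- and 4-fold between palbociclib-resistant Y537S and WT cells. It made 7 false calls of 136. For palbociclib resistance in WT cells it recovered 44.8%, 74.6% and 98.5%, with 10 false calls of 155. DESeq2 made 24 false calls of 179 and 36 of 196 on the same data. The real groups differed in spread and many more genes changed, so these rates may not hold for the real comparisons.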

Results

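MCF7 is an estrogen-receptor-positive breast cancer line. The cells sequenced here carried a doxycycline-inducible, HA-tagged gene for the Y537S form of the estrogen receptor (ER), a hormone-binding-domain change that keeps the receptor active without estrogen. Y537S libraries came from cells given doxycycline and wild-type (WT) libraries from the same engineered cells without it. Palbociclib and abemaciclib block the kinases CDK4 and CDK6, which take cells into DNA replication. Cells were resistant to palbociclib, resistant to abemaciclib or kept in vehicle, and bulk RNA was sequenced. The comparisons address what the Y537S receptor changes in resistant cells and how resistance to the 2 drugs differs. Levels are CPM, read counts scaled to library size, as mean ± SD over units. A unit is the libraries that share the first number in their titles. Fold changes are log2, with a standard error (SE) derived from the test statistic of the fit. In the pairwise comparisons, every gene named among the highest or lowest had all units of 1 group on the same side of all units of the other.

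The gene for ER itself, ESR1, fell with palbociclib resistance in WT cells. ESR1 was 273 ± 7.11 CPM (SD, n = 3) in WT vehicle cells and fell by 0.99 on the log2 scale (SE 0.17, adjusted p = 0.000493) to 138 ± 35.2 CPM (SD, n = 3) in palbociclib-resistant WT cells. It was 253 ± 13.2 CPM (SD, n = 3) in abemaciclib-resistant WT cells. In Y537S cells neither palbociclib resistance against vehicle nor abemaciclib against palbociclib resistance gave a called change: levels were 243 ± 10.2 CPM (SD, n = 3) in vehicle, 213 ± 25 CPM (SD, n = 2) with palbociclib resistance and 195 ± 57.7 CPM (SD, n = 2) with abemaciclib resistance. Counts per gene do not separate the tagged Y537S copy from the cell's own ESR1. In vehicle the Y537S libraries had no more ESR1 than the WT ones (-0.17 ± 0.17 SE, adjusted p = 0.733), so the counts do not show that the construct was induced there, and Y537S names the libraries as labelled. The deposited Cufflinks table gave another order. There, ESR1 was 37.1 ± 1.11 FPKM (SD, n = 3) in WT vehicle cells, 32.8 ± 2.59 FPKM (SD, n = 3) in Y537S vehicle cells, 59.9 ± 8.54 FPKM (SD, n = 2) in palbociclib-resistant and 68.8 ± 41.6 FPKM (SD, n = 2) in abemaciclib-resistant Y537S cells. The ratio of FPKM to CPM ran from 0.256 to 0.416 in the 4 resistant Y537S units and from 0.118 to 0.142 in the other 12.

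**Figure D1:**
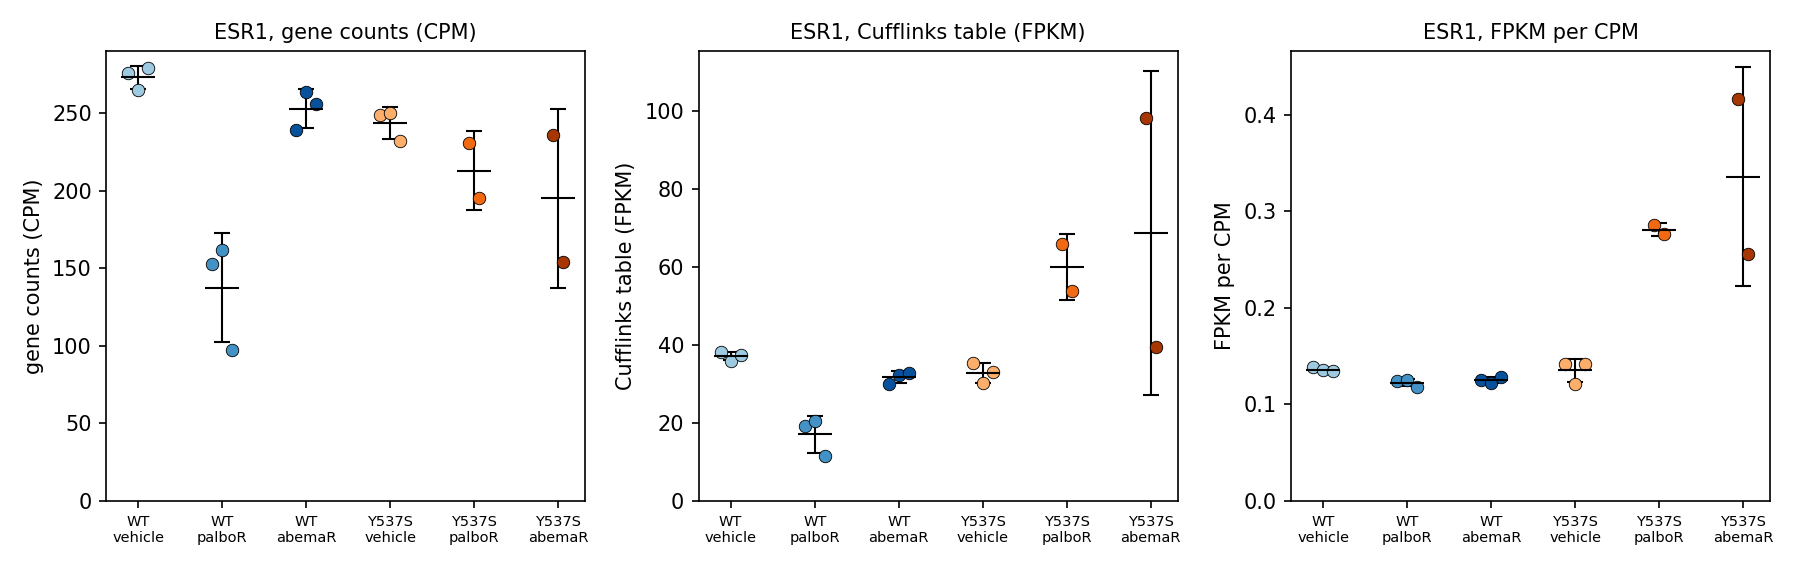
ESR1 per unit in CPM, in FPKM and as FPKM per CPM in the 6 groups; points are units and bars show mean and SD. FPKM per CPM is 0.256 or more in each resistant Y537S unit and 0.142 or less in every other unit.

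Palbociclib-resistant WT cells expressed less of the replication program and of CDK4, and more of cyclin D1, p21, TFF1 and genes of stress and the lysosome, than vehicle cells. CDK4, a target of the drug, fell by 0.94 (SE 0.13, adjusted p = 9.77e-05), from 365 ± 22.6 to 190 ± 11.7 CPM (SD, n = 3 and 3). CCND1, whose product cyclin D1 activates that kinase, rose by 1.22 ± 0.15 (SE, adjusted p = 3.73e-05) to 1620 ± 222 CPM (SD, n = 3). CDK6 rose by 0.85 ± 0.16 (SE, adjusted p = 0.00081), and CDKN1A, which encodes the cyclin-kinase inhibitor p21, rose by 1.34 ± 0.17 (SE, adjusted p = 4.73e-05). No change was called for RB1, the substrate of CDK4 and CDK6, at -0.42 ± 0.4 (SE, adjusted p = 0.434). Its level ran from 11.8 CPM in palbociclib-resistant unit 2 to 63.5 CPM in unit 1. The fold change was 0 without unit 2 and -0.97 without unit 1, neither called. The list of CDK4 and CDK6 axis genes as a whole held 9 genes that rose and 10 that fell, and camera did not call it (adjusted p = 0.641). CCNE1, for the G1/S cyclin E1, rose by 0.93 ± 0.3 (SE, adjusted p = 0.0271), but without any of WT vehicle units 1, 2 and 3 or palbociclib-resistant WT unit 1 it was not called (0.97, 0.95, 0.86 and 0.38). The estrogen response list, with 16 of 50 up and 6 down, was not called (camera adjusted p = 0.264). TFF1, a secreted peptide induced by estrogen, rose by 3.16 ± 0.32 (SE, adjusted p = 1.18e-05), from 153 ± 18.6 to 1360 ± 554 CPM (SD, n = 3 and 3), while PGR, the progesterone receptor, fell by 0.95 (SE 0.22, adjusted p = 0.00392).

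The highest fold changes in that comparison belonged to SFTPA2, a surfactant protein whose sequence is shared with SFTPA1 (7.37 ± 0.92 SE), COL21A1, a collagen (5.56 ± 0.89 SE), and AOX1, an aldehyde oxidase that metabolizes drugs (5.52 ± 0.61 SE). LUM, for the matrix proteoglycan lumican, rose from 0.609 ± 0.0608 to 13 ± 4.31 CPM (SD, n = 3 and 3). LUM stood in a list of immune, endothelial and fibroblast markers, in which 3 of 9 genes rose and 2 fell, and which was not called (adjusted p = 0.154). SLC6A14, an amino acid transporter, fell by 5.75 (SE 0.97) and SOX2, a stem-cell transcription factor, by 5.29 (SE 0.56). Of 49 E2F targets and DNA replication genes, 1 rose and 32 fell over all genes, and 1 rose and 35 fell adjusted over the list alone (camera adjusted p = 1.91e-10; adjusted p = 0.494 with an estimated correlation). CDC45, a part of the replicative helicase, fell by 1.37 (SE 0.17), and MCM4, another part, by 0.74 (SE 0.09). The G2/M and mitosis list followed, with 1 of 41 genes up and 22 down, or 1 and 27 adjusted over the list alone (camera adjusted p = 5.44e-07; adjusted p = 0.652 with an estimated correlation). Palbociclib-resistant unit 3 carried much of that fall: the list's median level was -0.66 there, 0 and 0.01 in units 1 and 2 and 0.23 to 0.27 in vehicle units. Without unit 3 the fold change moved from -0.43 to -0.22, still called, in leave-outs chosen after the data were seen. FOXM1, a mitotic transcription factor, fell by 0.94 (SE 0.16) and CDC25B, a phosphatase for mitotic entry, rose by 0.65 ± 0.1 (SE).

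Lysosome genes rose with palbociclib resistance in WT cells: 23 of 35 rose and none fell, or 24 and 0 adjusted over the list alone (camera adjusted p = 3.93e-06; adjusted p = 0.494 with an estimated correlation). Without palbociclib-resistant unit 3 the median moved from 0.6 to 0.37, still called. Among them were TFEB, a master regulator of lysosomes (2.05 ± 0.33 SE), and NEU1, a lysosomal sialidase (0.92 ± 0.14 SE). Of 25 p53 targets, 13 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 7.18e-05; adjusted p = 0.494 with an estimated correlation). GDF15, a stress-induced cytokine, rose by 3.75 ± 0.43 (SE) to 179 ± 100 CPM (SD, n = 3). Hypoxia and glycolysis genes rose in 17 and fell in 1 of 32 cases, the same adjusted over the list alone (camera adjusted p = 0.000984; adjusted p = 0.494 with an estimated correlation), with NDRG1, a hypoxia-induced gene, at 2.44 ± 0.29 (SE). The unfolded protein and integrated stress response list had 11 of 27 up and 2 down, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.494 with an estimated correlation). ATF4, the transcription factor of that response, rose by 0.57 ± 0.09 (SE). That list was not called without palbociclib-resistant unit 1 (median 0.39, then 0.32).

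Signalling genes rose as well in palbociclib-resistant WT cells. Of 23 MAPK output genes, 9 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.494 with an estimated correlation), led by IER3, an early-response gene, at 3.28 ± 0.27 (SE, adjusted p = 2.68e-06). Receptor tyrosine kinases and ligands had 11 of 27 up and 2 down, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.494 with an estimated correlation). ERBB4, a receptor of the EGFR family, rose by 2.85 ± 0.31 (SE) to 19.5 ± 8.14 CPM (SD, n = 3). Inflammatory and NF-kB genes had 9 of 17 up and 1 down, the same adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.494 with an estimated correlation). NFKB2, an NF-kB subunit, rose by 1.73 ± 0.19 (SE), while NFKB1, another subunit, fell by 0.78 (SE 0.13). The luminal identity list had 14 of 28 up and 3 down, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.0415; adjusted p = 0.494 with an estimated correlation), with MUC1, an epithelial mucin, at 1.88 ± 0.31 (SE) and ESR1 among those that fell. The MAPK list was not called without palbociclib-resistant unit 2 (median 0.58, then 0.55), nor the luminal list when any 1 of the palbociclib-resistant units or vehicle unit 2 was left out (0.3, then 0.3 to 0.39). In all, 4982 of 14173 genes changed, 2693 higher and 2289 lower. By the Cufflinks values 31.7% of the called genes were higher, against 54.1% here. The batch-corrected STAR table gave 1825 genes.

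**Figure D2:**
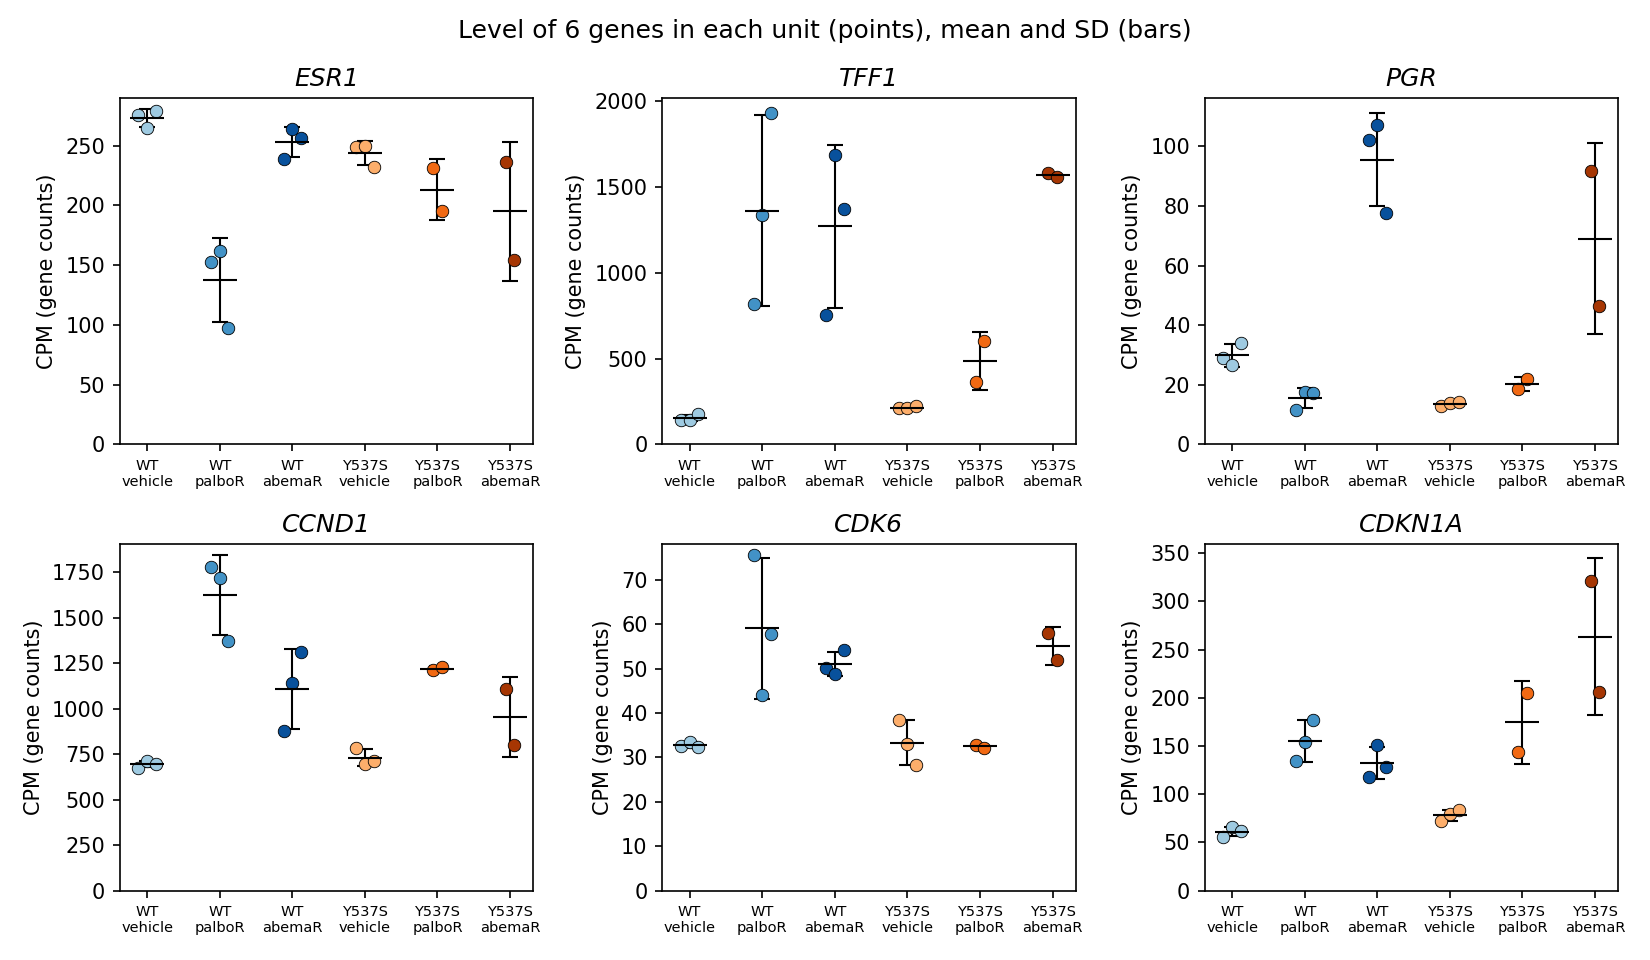
CPM of ESR1, TFF1, PGR, CCND1, CDK6 and CDKN1A in the 6 groups; points are units and bars show mean and SD. TFF1 averages 153 CPM in WT vehicle cells and 1360 CPM in palbociclib-resistant WT cells.

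Palbociclib-resistant Y537S cells shared with WT cells the rise of cyclin D1, p21, lysosome and p53-target genes, and expressed more interferon-stimulated and antigen-presentation genes than Y537S vehicle cells. CCND1 rose by 0.74 ± 0.16 (SE, adjusted p = 0.00398) to 1220 ± 11.1 CPM (SD, n = 2) and CDKN1A by 1.15 ± 0.18 (SE, adjusted p = 0.000482). CCNE2, for the G1/S cyclin E2, rose by 1.12 ± 0.24 (SE, adjusted p = 0.00414), from 39 ± 8.14 (SD, n = 3) to 84.7 ± 8.38 CPM (SD, n = 2). IFI27, an interferon-induced mitochondrial protein, rose by 4.18 ± 0.45 (SE, adjusted p = 5.07e-05) to 333 ± 54.1 CPM (SD, n = 2). BIRC3, an NF-kB-induced inhibitor of apoptosis, rose by 3.3 ± 0.5 (SE, adjusted p = 0.000386). GABRP, a GABA receptor subunit found in basal-like tumours, fell by 6.3 (SE 0.42, adjusted p = 7.9e-07), and IGFBP5, a secreted binder of insulin-like growth factors, by 4.56 (SE 0.38, adjusted p = 5.95e-06). TFF1 rose by 1.18 ± 0.32 (SE, adjusted p = 0.0155), a call lost without palbociclib-resistant unit 3 (0.77). APOL1, an interferon-induced apolipoprotein, and LUM had the highest fold changes, 5.4 ± 0.57 and 4.77 ± 0.52 (SE).

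Of 49 interferon-stimulated genes, 15 rose and none fell with palbociclib resistance in Y537S cells, or 16 and 0 adjusted over the list alone (camera adjusted p = 0.00046; adjusted p = 0.691 with an estimated correlation). SAMD9, an antiviral factor, rose by 2.29 ± 0.26 (SE). In the antigen presentation list 10 of 28 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00236; adjusted p = 0.673 with an estimated correlation), with HLA-E, an HLA class I gene, at 0.66 ± 0.13 (SE). Estrogen-response genes were called, with 17 of 50 up and 6 down, or 19 and 7 adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.571 with an estimated correlation). STC2, a secreted glycoprotein, rose by 1.47 ± 0.2 (SE) to 393 ± 62.2 CPM (SD, n = 2). Lysosome genes rose in 15 of 35 cases and fell in none, or 17 and 0 adjusted over the list alone (camera adjusted p = 0.000196; adjusted p = 0.5 with an estimated correlation), NPC1, the lysosomal cholesterol exporter, at 1.03 ± 0.15 (SE). P53 targets had 11 of 25 up and 2 down, the same adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.494 with an estimated correlation), and RRM2B, a ribonucleotide reductase subunit, rose by 0.63 ± 0.12 (SE). Of 17 inflammatory and NF-kB genes 7 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.494 with an estimated correlation). Their median moved from 1.19 to 0.75 without palbociclib-resistant unit 3, still called. E2F targets and DNA replication genes were not called in Y537S cells: 4 of 49 rose and 3 fell, or 3 and 3 adjusted over the list alone (median 0.03, with camera's direction down, adjusted p = 0.849). In all, 3758 genes changed, 2078 higher and 1680 lower. With WT cells it shared 1260 genes that were higher in both (395 expected by chance) and 826 lower in both (271 expected), and 84 went opposite ways (655 expected). Without palbociclib-resistant unit 1 the count was 2159, and without unit 3 it was 1642, each leaving 1 unit in that group. It was 1033 in the batch-corrected STAR table.

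In vehicle, Y537S cells had much lower interferon-stimulated genes than WT cells. IFI27 fell by 4.95 (SE 0.45, adjusted p = 0.000166), from 565 ± 30.7 to 18.3 ± 11.7 CPM (SD, n = 3 and 3). OAS2, a sensor of double-stranded RNA, fell by 4.69 (SE 0.69, adjusted p = 0.0056), RSAD2, the antiviral enzyme viperin, by 4.63 (SE 0.74, adjusted p = 0.00699), and BST2, a tether of budding virus, by 3.99 (SE 0.44, adjusted p = 0.000632). ISG15, a ubiquitin-like interferon product, fell by 2 (SE 0.22, adjusted p = 0.00038). Of 49 genes on that list, 32 fell and none rose, or 45 and 0 adjusted over the list alone (camera adjusted p = 5.67e-93; adjusted p = 0.174 with an estimated correlation), with a median of -1.59. Going the other way, KRT81, a hair keratin, rose by 3.35 ± 0.48 (SE, adjusted p = 0.00553), GABRP by 2.67 ± 0.28 (SE, adjusted p = 0.000324), and CEACAM6, an adhesion molecule close in sequence to CEACAM5, by 2.36 ± 0.32 (SE, adjusted p = 0.00399) to 211 ± 30.5 CPM (SD, n = 3). PGR fell by 1.14 (SE 0.22, adjusted p = 0.018). Without WT unit 1 or 3, or Y537S unit 1, 2 or 3, PGR was not called (-1.17, -1.04, -1.1, -1.15 and -1.18).

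The other lists called in vehicle cells moved less. Lists of mitochondrially encoded and histone genes, respiration and inflammation were also called here and are given under other observations. Y537S vehicle library 2_2 had a mitochondrial share of 20.9%, against 7.82% to 11.4% in the others of its group. Antigen presentation genes fell in 3 of 28 cases, or 7 adjusted over the list alone, and none rose (camera adjusted p = 2.07e-07; adjusted p = 0.494 with an estimated correlation). E2F targets and DNA replication genes had a median of -0.19 with 0 of 49 called over all genes and 0 adjusted over the list alone (camera adjusted p = 1.87e-06; adjusted p = 0.63 with an estimated correlation), and TK1, thymidine kinase, was -0.37 ± 0.11 (SE, adjusted p = 0.138). G2/M and mitosis genes had a median of -0.17, with 0 called over all genes and 2 of 41 lower adjusted over the list alone (camera adjusted p = 1.32e-05; adjusted p = 0.69 with an estimated correlation). The estrogen response list was not called: 1 of 50 genes fell and none rose (camera adjusted p = 0.097). P53 targets had 1 of 25 up, or 2 adjusted over the list alone, and none down (camera adjusted p = 0.0152; adjusted p = 0.494 with an estimated correlation), a call lost without Y537S unit 3 (median 0.13, then 0.1). Receptor tyrosine kinases and ligands had 1 of 27 up, or 2 adjusted over the list alone, and none down (camera adjusted p = 0.0125; adjusted p = 0.494 with an estimated correlation). In all, 172 genes changed, 98 higher and 74 lower, a share of 57% higher against 45.8% by the Cufflinks values. Leaving out WT units 1, 2 and 3 in turn left 47, 60 and 52, and leaving out Y537S units 1, 2 and 3 left 72, 60 and 90. DESeq2 called 457, and a fit of only these 2 groups called 1677. Every Y537S library had doxycycline and no WT library did, so in each Y537S comparison the receptor and doxycycline cannot be told apart.

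In palbociclib-resistant cells, the Y537S cells had more replication-gene and less protein-folding-stress expression than WT cells. STAT6, a transcription factor of interleukin signalling, was 73.3 ± 19 CPM (SD, n = 2) against 3.86 ± 3.36 CPM (SD, n = 3), a rise of 4.31 ± 0.6 (SE, adjusted p = 0.000631). SLC6A14 was higher by 6.87 ± 1.02 (SE, adjusted p = 0.000967), SHH, a secreted morphogen, by 3.89 ± 0.55 (SE, adjusted p = 0.00071), and MAPK13, a stress-activated kinase, by 3.82 ± 0.37 (SE, adjusted p = 2.47e-05). Lower were PSAT1, an enzyme of serine synthesis, which fell by 5.18 (SE 0.6, adjusted p = 0.000158) from 84 ± 14.5 (SD, n = 3) to 2.31 ± 1.34 CPM (SD, n = 2), and TIMP3, an inhibitor of matrix proteases, which fell by 3.16 (SE 0.35, adjusted p = 8.72e-05). The estrogen-responsive growth gene GREB1 fell by 0.9 (SE 0.15, adjusted p = 0.00133). TFF1 fell by 1.49 (SE 0.35, adjusted p = 0.0134), a call lost without Y537S unit 1 (-1.17). ESR1 rose by 0.63 ± 0.19 (SE, adjusted p = 0.0404), a call lost without WT unit 3 (0.43) or Y537S unit 1 (0.5) or 3 (0.75). CDK6 fell by 0.86 (SE 0.18, adjusted p = 0.00647) and was not called without Y537S unit 1 (-0.88) or 3 (-0.85).

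E2F targets and DNA replication genes rose in 10 of 49 cases and fell in none, or 17 and 0 adjusted over the list alone (camera adjusted p = 1.38e-06; adjusted p = 0.621 with an estimated correlation). TYMS, which makes thymidylate for DNA, was 154 ± 25.9 CPM (SD, n = 2) against 77.5 ± 20.2 CPM (SD, n = 3), higher by 0.99 ± 0.17 (SE, adjusted p = 0.002). Without WT unit 3 the median of the list moved from 0.3 to 0.13, still called. The interferon-stimulated list had 1 gene up and 14 of 49 down, or 1 and 25 adjusted over the list alone (camera adjusted p = 6.19e-08; adjusted p = 0.63 with an estimated correlation). Its median level did not separate the units: WT unit 3 (-0.95) lay below both Y537S units (-0.87 and -0.9) and WT units 1 and 2 (0.46 and -0.17) above them. The difference over units was -0.66 ± 0.41 (SE). Of 27 unfolded protein and integrated stress response genes, 10 fell and none rose, or 13 and 1 adjusted over the list alone (camera adjusted p = 2.61e-06; adjusted p = 0.494 with an estimated correlation). The estrogen response list, with 6 of 50 up and 9 down, was not called (camera adjusted p = 0.654). In all, 1580 genes changed, 880 higher and 700 lower, and by the Cufflinks values 71.5% of the called genes were higher, against 55.7% here. The count was 673 without Y537S unit 1, 477 without unit 3, 324 when only these 2 groups were fitted and 340 in the batch-corrected STAR table.

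In abemaciclib-resistant cells the direction of the replication genes was the opposite. Y537S cells had less E2F and mitotic expression than WT cells, and more basal-epithelial expression. Y537S unit 1 carried more of the E2F fall: that list's median level was -0.55 there, -0.17 in Y537S unit 2 and 0.1 to 0.15 in WT units. RRM2, a ribonucleotide reductase subunit, fell by 0.9 (SE 0.14, adjusted p = 0.000847), from 286 ± 15.7 (SD, n = 3) to 154 ± 8.8 CPM (SD, n = 2), and KIF2C, a mitotic kinesin, by 1.15 (SE 0.15, adjusted p = 0.00031). E2F targets and DNA replication genes fell in 24 of 49 cases and rose in 1, or 27 and 1 adjusted over the list alone (camera adjusted p = 4.34e-11; adjusted p = 0.494 with an estimated correlation). G2/M and mitosis genes fell in 20 of 41 and rose in none, or 26 and 0 adjusted over the list alone (camera adjusted p = 1.74e-11; adjusted p = 0.494 with an estimated correlation). Of 23 basal and myoepithelial genes, 11 rose and none fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 9.72e-05; adjusted p = 0.494 with an estimated correlation). Their median moved from 1.15 to 0.49 without Y537S unit 1, still called. TRIM29, a basal-cell ubiquitin ligase, was 48.3 ± 8.83 CPM (SD, n = 2) against 9.76 ± 1.43 CPM (SD, n = 3), and ITGA6, a laminin-binding integrin, rose by 2.12 ± 0.28 (SE, adjusted p = 0.000314). CEACAM6 was 536 ± 16.3 CPM (SD, n = 2) against 45.9 ± 6.82 CPM (SD, n = 3), and its neighbour in sequence CEACAM5 rose by 3.75 ± 0.45 (SE, adjusted p = 0.000225). PSAT1 had 2 counts in the Y537S units, and its CPM was lower by a ratio of 4530 (95% counting interval 1250 to 37400). CDKN1A rose by 0.99 ± 0.18 (SE, adjusted p = 0.00234), a call lost without Y537S unit 1 (0.64), as was that of CCNE1 (1.31 ± 0.33 SE, 0.74 without it).

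Of 49 interferon-stimulated genes, 4 fell and none rose between abemaciclib-resistant genotypes, the same adjusted over the list alone (camera adjusted p = 0.0129; adjusted p = 0.739 with an estimated correlation). The list's median level differed by -0.23 ± 0.24 (SE over units), the units overlapped, and the call was lost without WT unit 1 or Y537S unit 2. Of 28 antigen presentation genes 9 fell and none rose, or 12 and 0 adjusted over the list alone (camera adjusted p = 0.000474; adjusted p = 0.605 with an estimated correlation), among them CALR, a chaperone of the endoplasmic reticulum, which fell by 0.7 (SE 0.1, adjusted p = 0.000454). The units of that list overlapped as well: its median level was 0.49 and 0.81 in Y537S units and 0.52 to 1.38 in WT units, in log2 relative to the mean of all units. The unfolded protein and integrated stress response list had 3 of 27 up and 7 down, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.0302; adjusted p = 0.564 with an estimated correlation), a call lost without Y537S unit 2. The estrogen response list had 9 of 50 up and 13 down and was not called (camera adjusted p = 0.155). In all, 2894 genes changed, 1599 higher and 1295 lower, a share of 55.3% higher against 66% in the Cufflinks table, and both groups were of batch 2. Of the genes called between Y537S and WT cells, 277 were higher (99.3 expected) and 131 lower (64 expected) under both drugs. A further 103 went opposite ways (159 expected). Over all genes tested the fold changes of both comparisons were only weakly related (Pearson correlation 0.297, Spearman 0.15). The count was 1802, 1905 and 1905 without WT units 1, 2 and 3, 1111 without Y537S unit 1, 1539 when only these 2 groups were fitted, and 6316 in the batch-corrected STAR table.

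**Figure D3:**
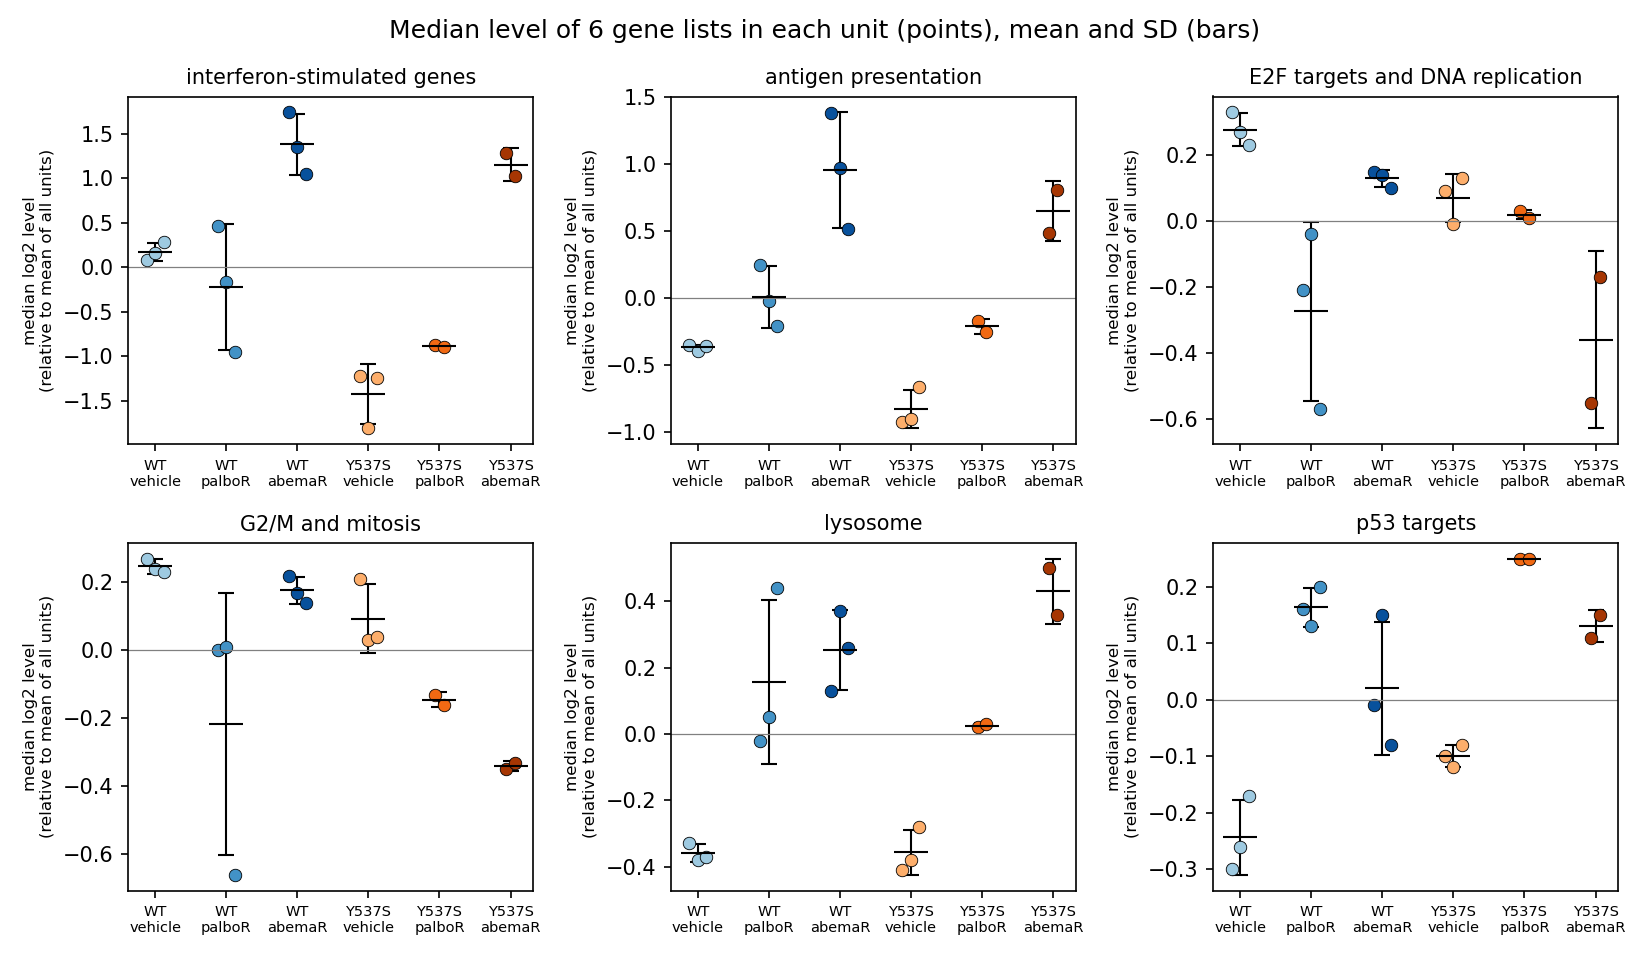
Median log2 level of 6 gene lists in each unit, relative to the mean of all units, in the 6 groups. The interferon-stimulated list has a median fold change of -1.59 between Y537S and WT vehicle cells and of 1.37 and 1.87 between abemaciclib- and palbociclib-resistant WT and Y537S cells.

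Between the drugs, abemaciclib-resistant WT cells had far higher interferon-stimulated and antigen-presentation genes, and more ER and progesterone receptor expression, than palbociclib-resistant WT cells, each at 1 µM. PGR rose by 2.63 ± 0.23 (SE, adjusted p = 3.83e-06), from 15.5 ± 3.48 to 95.4 ± 15.5 CPM (SD, n = 3 and 3), GREB1 by 0.94 ± 0.13 (SE, adjusted p = 0.00013) and ESR1 by 0.88 ± 0.17 (SE, adjusted p = 0.00145). CDK4 rose by 0.78 ± 0.13 (SE, adjusted p = 0.000531) to 328 ± 8.84 CPM (SD, n = 3). CCND1 fell by 0.55 (SE 0.15, adjusted p = 0.0105), and without abemaciclib-resistant unit 1 it was not called (-0.41). The difference in TFF1 was -0.1 (95% interval -0.68 to 0.47), in CDKN1A -0.23 (95% interval -0.55 to 0.1), in CCNE1 -0.06 (95% interval -0.65 to 0.52) and in CDK6 -0.21 (95% interval -0.52 to 0.09), none of them called. RSAD2 rose by 4.53 ± 0.61 (SE, adjusted p = 0.000173) to 85.8 ± 27.4 CPM (SD, n = 3). BCL2, an anti-apoptotic gene induced by estrogen, rose by 4.72 ± 0.52 (SE, adjusted p = 3.26e-05), and AGR3, a disulfide isomerase of luminal tumours, by 4.57 ± 0.58 (SE, adjusted p = 0.000104). Among the lowest, TIMP3 fell by 3.53 (SE 0.31, adjusted p = 4.32e-06) and ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, by 4.22 (SE 0.44, adjusted p = 2.33e-05).

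Of 49 interferon-stimulated genes, 43 rose and none fell between the drugs in WT cells, or 44 and 0 adjusted over the list alone (camera adjusted p = 7.14e-21; adjusted p = 0.494 with an estimated correlation). Antigen presentation genes rose in 23 of 28 cases and fell in none, or 24 and 0 adjusted over the list alone (camera adjusted p = 4.34e-11; adjusted p = 0.494 with an estimated correlation). CD74, the class II invariant chain, rose by 3.73 ± 0.54 (SE). Estrogen-response genes had 24 of 50 up and 8 down, the same adjusted over the list alone (camera adjusted p = 6.82e-05; adjusted p = 0.494 with an estimated correlation), CXCL12, an estrogen-induced chemokine, at 1.68 ± 0.15 (SE). E2F targets and DNA replication genes rose in 24 of 49 cases and fell in none, or 26 and 0 adjusted over the list alone (camera adjusted p = 4.77e-07; adjusted p = 0.592 with an estimated correlation). The G2/M and mitosis list had 15 of 41 up and none down, or 17 and 0 adjusted over the list alone (camera adjusted p = 4.52e-05; adjusted p = 0.69 with an estimated correlation), and MKI67, the proliferation marker Ki-67, rose by 0.68 ± 0.15 (SE). Without palbociclib-resistant unit 3 the G2/M median moved from 0.33 to 0.12 and the E2F median from 0.38 to 0.22, both still called. The estrogen response median moved from 0.39 to 0.21 without abemaciclib-resistant unit 3, still called. Lists that fell were MAPK output (2 of 23 up and 9 down, the same adjusted over the list alone; camera adjusted p = 0.0383; adjusted p = 0.494 with an estimated correlation) and hypoxia and glycolysis (0 of 32 up and 13 down, or 14 down adjusted over the list alone; camera adjusted p = 0.00113; adjusted p = 0.494 with an estimated correlation). The MAPK call was lost without palbociclib-resistant unit 2 or 3 or abemaciclib-resistant unit 2, and the hypoxia median moved from -0.33 to -0.2 without palbociclib-resistant unit 3, still called. The mitochondrial share of counts moved with the drugs: 11% to 12% in abemaciclib-resistant and 7.65% to 10.2% in palbociclib-resistant WT libraries. IER3 fell by 3.05 (SE 0.27) and PFKFB3, an activator of glycolysis, by 1.52 (SE 0.15). In all, 4553 genes changed, 2190 higher and 2363 lower. All abemaciclib libraries were of batch 2 and all others of batch 1, so drug and batch cannot be told apart here. The deposited batch-corrected tables gave 708 (STAR) and 864 (Cufflinks) genes, of which 37.7% and 59.7% were higher, against 48.1% here. Of the genes named, GREB1, ESR1, CCND1, ALDH1A3, PFKFB3 and CD74 were called in neither of those tables. PGR, RSAD2 and BCL2 were called only in the STAR one and CDK4 only in the Cufflinks one. Since batch and drug coincide, a correction for batch can take out a drug difference as well. A call lost in those tables therefore does not show that the gene is alike between the drugs.

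In Y537S cells, abemaciclib resistance again came with higher interferon-stimulated genes than palbociclib resistance, but with lower replication genes. The mitochondrial share of counts was again higher, 10.8% to 12.7% against 6.85% to 9.43%. Among interferon-stimulated genes, 43 of 49 rose and 1 fell, or 44 and 2 adjusted over the list alone (camera adjusted p = 5.73e-25; adjusted p = 0.494 with an estimated correlation). SAMD9 rose by 2.38 ± 0.3 (SE, adjusted p = 0.000134) to 388 ± 40.8 CPM (SD, n = 2), and RSAD2 by 5.01 ± 0.77 (SE, adjusted p = 0.000656). Antigen presentation genes rose in 10 of 28 cases and fell in none, or 12 and 0 adjusted over the list alone (camera adjusted p = 6.22e-06; adjusted p = 0.494 with an estimated correlation), with TAP2, a peptide transporter, at 1.56 ± 0.25 (SE, adjusted p = 0.00074). E2F targets and DNA replication genes fell in 20 of 49 cases and rose in 1, or 23 and 1 adjusted over the list alone (camera adjusted p = 1.16e-05; adjusted p = 0.673 with an estimated correlation). TYMS fell by 1.28 (SE 0.19, adjusted p = 0.000448) to 63.6 ± 5.97 CPM (SD, n = 2). The list's median level was -0.55 and -0.17 in abemaciclib-resistant units 1 and 2, and 0.03 and 0.01 in palbociclib-resistant units 1 and 3. G2/M and mitosis genes had 1 of 41 up and 7 down, the same adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.735 with an estimated correlation), with CDC20, an activator of the anaphase-promoting complex, at -1.07 ± 0.14 (SE, adjusted p = 0.000138).

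PGR, GREB1 and TFF1 were higher with abemaciclib in Y537S cells, but the estrogen response list, with 15 of 50 up and 6 down, was not called (camera adjusted p = 0.0624). PGR rose by 1.77 ± 0.27 (SE, adjusted p = 0.000486) and GREB1 by 1.19 ± 0.16 (SE, adjusted p = 0.000191) to 1050 ± 156 CPM (SD, n = 2). TFF1 rose by 1.7 ± 0.37 (SE, adjusted p = 0.00485), a call lost without palbociclib-resistant unit 1 (1.38). The difference in ESR1 was -0.13 (95% interval -0.53 to 0.28) and in RB1 0.1 (95% interval -0.85 to 1.05), neither called. The ER construct and pathway list had 4 of 9 genes up and none down, the same adjusted over the list alone (camera adjusted p = 0.0226; adjusted p = 0.494 with an estimated correlation), as against 3 up and 2 down in WT cells, the same adjusted over the list alone (camera adjusted p = 0.0386; adjusted p = 0.494 with an estimated correlation). Both calls were lost without at least 1 unit. MSMB, a secreted prostate protein, rose by 5.29 ± 0.74 (SE, adjusted p = 0.000348) to 201 ± 40.7 CPM (SD, n = 2). Among the lowest, FGFR2, a fibroblast growth factor receptor, fell by 3.83 (SE 0.36, adjusted p = 1.5e-05) and LOXL1, a collagen cross-linker, by 3.59 (SE 0.26, adjusted p = 2.41e-06). The mesenchymal and EMT list had 1 of 30 up and 7 down, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.0416; adjusted p = 0.494 with an estimated correlation). It was not called without palbociclib-resistant unit 3 or abemaciclib-resistant unit 2 (median -0.57, then -0.35 or -0.73). The same list in WT cells had 1 up and 10 down, or 1 and 11 adjusted over the list alone (camera adjusted p = 0.0125; adjusted p = 0.494 with an estimated correlation). In all, 3438 genes changed in Y537S cells, 1799 higher and 1639 lower, of which 729 were also higher (278 expected) and 667 also lower (273 expected) in WT cells and 151 went opposite ways (553 expected). Drug and batch cannot be told apart here either. The batch-corrected tables gave 1810 (STAR) and 754 (Cufflinks) genes. PGR, GREB1, TFF1 and TAP2 were called in neither, and RSAD2 and CDC20 only in the STAR one. Here too the correction can take out a drug difference, so a lost call decides nothing about the drug. The count was 1906, 1662 and 2189 without palbociclib-resistant unit 1 or 3 or abemaciclib-resistant unit 1, and 1014 when only these 2 groups were fitted.

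**Figure D4:**
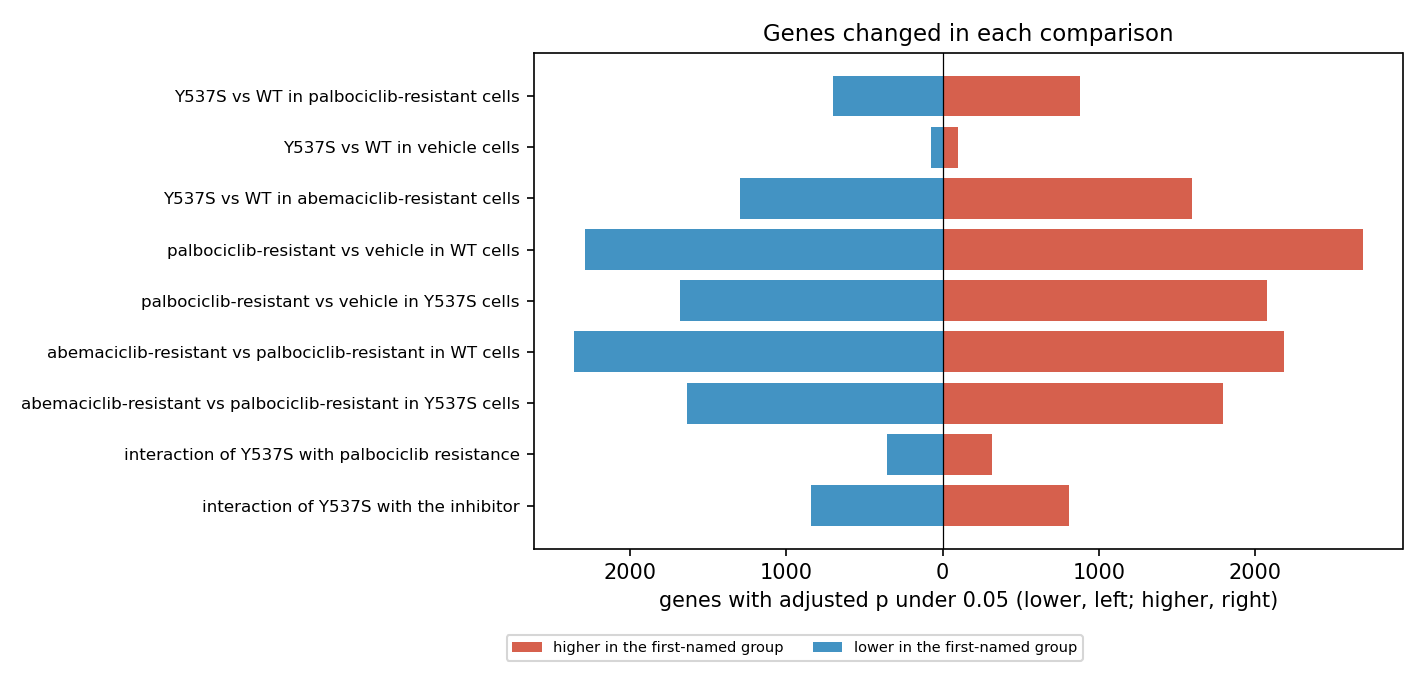
Number of genes higher and lower at an adjusted p under 0.05 in each comparison. The bars add up to 172 genes for Y537S against WT in vehicle and to 4982 for palbociclib resistance in WT cells. All bars are from the single fit of 6 groups. Fitted alone, Y537S against WT gave 1677 genes in vehicle and 324 in palbociclib-resistant cells.

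Tests of the difference between the genotypes' responses found that replication genes, which fell with palbociclib resistance in WT cells and were not called in Y537S cells, differed in their response. Relative to the WT response, the Y537S response was higher for 10 of 49 E2F targets and DNA replication genes and lower for none, or 22 and 0 adjusted over the list alone (camera adjusted p = 9.94e-13; adjusted p = 0.494 with an estimated correlation). GINS2, a helicase cofactor, differed by 1 ± 0.19 (SE, adjusted p = 0.00814), and MYBL2, a cell-cycle transcription factor, by 1.63 ± 0.29 (SE, adjusted p = 0.00619). MYBL2 came from the G2/M list, where 2 of 41 were higher and none lower, the same adjusted over the list alone (camera adjusted p = 0.000785; adjusted p = 0.691 with an estimated correlation). That call rests on palbociclib-resistant WT unit 3: without it the median moved from 0.22 to 0.06 and was not called (adjusted p = 0.4). The E2F median moved from 0.42 to 0.27 without that unit, still called. IFI27 differed by 4.89 ± 0.59 (SE, adjusted p = 0.00125), one of 4 interferon-stimulated genes higher and none lower, or 6 and 0 adjusted over the list alone (camera adjusted p = 1.48e-10; adjusted p = 0.545 with an estimated correlation). PSAT1 differed by -4.54 ± 0.69 (SE, adjusted p = 0.00311), and 6 of 27 unfolded protein and integrated stress response genes were lower and none higher, or 13 and 0 adjusted over the list alone (camera adjusted p = 8.66e-07; adjusted p = 0.494 with an estimated correlation). For PGR, which fell in WT cells, the difference was 1.53 ± 0.33 (SE, adjusted p = 0.0171), and without palbociclib-resistant Y537S unit 3 it was not called (1.42). In all, 677 genes differed, 318 higher and 359 lower, a share of 47% higher against 73.2% in the Cufflinks table. The count was 253, 283 and 329 without WT vehicle units 1, 2 and 3, 1082 without palbociclib-resistant WT unit 3, 384 and 338 without Y537S vehicle units 1 and 2, and 269 and 166 without palbociclib-resistant Y537S units 1 and 3. DESeq2 gave 1278, and 66 were called in the batch-corrected STAR table.

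Between the drugs the genotypes differed in the replication genes, which abemaciclib-resistant cells expressed more than palbociclib-resistant cells in WT and less in Y537S. Of 49 E2F targets and DNA replication genes, 26 were lower in the Y537S response and none higher, or 33 and 1 adjusted over the list alone (camera adjusted p = 1.48e-20; adjusted p = 0.494 with an estimated correlation). TYMS differed by -1.8 ± 0.25 (SE, adjusted p = 0.00126) and TK1 by -1.07 ± 0.17 (SE, adjusted p = 0.00311). G2/M and mitosis genes were lower in 10 of 41 cases and higher in none, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.05e-10; adjusted p = 0.509 with an estimated correlation). Without palbociclib-resistant WT unit 3 their median moved from -0.61 to -0.38, still called. FKBP10, a collagen chaperone, differed by 5.37 ± 0.82 (SE, adjusted p = 0.00276), and DHRS2, a stress-induced reductase, by 5.18 ± 0.49 (SE, adjusted p = 0.00011). GJA1, the gap-junction protein of the connexin family, differed by -6.9 ± 1.24 (SE, adjusted p = 0.00537) and CLSTN2, a calcium-binding cadherin relative, by -4.06 ± 0.66 (SE, adjusted p = 0.00319). ESR1 differed by -1 ± 0.27 (SE, adjusted p = 0.0269), which was not called without abemaciclib-resistant WT unit 2 (-0.97) or 3 (-1), palbociclib-resistant Y537S unit 1 (-0.88) or 3 (-1.13), or abemaciclib-resistant Y537S unit 2 (-0.73). A batch shift that is the same in both genotypes cancels in this difference. In all, 1651 genes differed, 810 higher and 841 lower. The count was 2569 without palbociclib-resistant WT unit 2, 1067 and 1016 without abemaciclib-resistant WT units 2 and 3, 570 and 616 without palbociclib-resistant Y537S units 1 and 3, 1064 without abemaciclib-resistant Y537S unit 1, and 107 with abemaciclib and palbociclib groups fitted alone. It was 3206 in the batch-corrected STAR table.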

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

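Chosen after the result was seen were the tests of a single unit and of a like effect of doxycycline on interferon-stimulated genes, of a same-size batch shift, and, for ESR1, of a single unit in resistant cells, of construct reads or another transcript form there, and of construct reads alike in all Y537S units. Leaving out units in the list tests was chosen after the data were seen too. The rules that read a gap resting on 1 unit as open, in both other ESR1 tests, were also set after the values were seen. Each library's total, mitochondrial share and levels of the 11 genes named in every comparison were compared within groups of 4 to 6 libraries by the gap of the highest or lowest to its neighbour. Of 78 such tests, 6 found a library apart, and chance gives about 1 in 20, or 3.9. The totals were 83.9 M counts in palbociclib-resistant WT library 1_1 (others 19.4 M to 25 M) and 68.2 M in Y537S vehicle library 1_2 (others 19.7 M to 27.1 M). The mitochondrial shares were 10.5% in WT vehicle library 3_2 (others 7.24% to 8.28%) and 20.9% in Y537S vehicle library 2_2 (others 7.82% to 11.4%). CCND1 was 821 CPM in Y537S vehicle library 1_2 (others 670 to 725), and PGR was 37.5 CPM in WT vehicle library 3_1 (others 26.4 to 30.3).

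The response to palbociclib resistance differed between the genotypes, by a test of the difference itself, for 677 genes. Among the named genes it was more positive in Y537S cells for PGR (1.53), SLC6A14 (6.75), IFI27 (4.89), RSAD2 (4.46), FRAS1 (3.43), PLXNA2 (3.41) and WLS (3.36). It was more negative for CDK6 (-0.89), GREB1 (-0.79), TFF1 (-1.98), ADORA1 (-5.06), PSAT1 (-4.54), KRT81 (-4.49), GABRP (-3.58), DHRS2 (-3.51) and TIMP3 (-3.25). Some of these calls ended when a unit was left out: PGR without palbociclib-resistant Y537S unit 3 (1.42), ADORA1 without palbociclib-resistant Y537S unit 1 or 3 (-5.18, -4.94), and RSAD2 without either of these (4.51, 4.43), WT vehicle unit 1 (4.5) or Y537S vehicle unit 2 (4.23). TFF1 was not called without WT vehicle unit 1 or 2 (-1.91, -1.91), Y537S vehicle unit 1 (-1.98) or palbociclib-resistant Y537S unit 1 (-1.66). GREB1 was not called without WT vehicle unit 1 or 2 (-0.76, -0.73), Y537S vehicle unit 1, 2 or 3 (-0.74, -0.83, -0.79) or palbociclib-resistant Y537S unit 1 or 3 (-0.77, -0.79). CDK6 was not called without WT vehicle unit 1, 2 or 3 (-0.87, -0.89, -0.87), Y537S vehicle unit 1 or 2 (-0.77, -0.89) or palbociclib-resistant Y537S unit 1 or 3 (-0.9, -0.86). The lists that differed were E2F targets (median 0.42), G2/M and mitosis (0.22), interferon-stimulated genes (0.59), cholesterol biosynthesis (0.23), unfolded protein and integrated stress response (-0.51) and library composition (-0.59). None was called with an estimated correlation (adjusted p = 0.494 to 0.691). Without palbociclib-resistant WT unit 3 G2/M was not called (0.06), and without unit 2 of that group cholesterol biosynthesis was not (0.18). Library composition moved to -0.33 without Y537S vehicle unit 2, still called. E2F targets moved to 0.27 without palbociclib-resistant WT unit 3, and interferon-stimulated genes to 0.99 and 0.33 without its units 1 and 3, all still called.

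The difference between abemaciclib and palbociclib resistance differed between the genotypes for 1651 genes. It was more positive in Y537S cells for CDK6 (0.97), TFF1 (1.8), SFTPA2 (7.68), FKBP10 (5.37), DHRS2 (5.18), SCIN (5.14), KIAA1199 (4.99) and ADORA1 (4.53). It was more negative for ESR1 (-1), CCNE2 (-1.58), SLC6A14 (-7), GJA1 (-6.9), ARHGAP36 (-4.21), CLSTN2 (-4.06), ELOVL2 (-3.94) and PSAT1 (-6.83, a fitted value with 2 counts in abemaciclib-resistant Y537S units, so not a measure of its size). Without palbociclib-resistant Y537S unit 1, calls ended for ESR1 (-0.88), CDK6 (0.99), TFF1 (1.48), SCIN (5.12), ADORA1 (4.65), ARHGAP36 (-4.19) and ELOVL2 (-3.84). Without unit 3 of that group they ended for ESR1 (-1.13), CDK6 (0.95), CCNE2 (-1.48), SFTPA2 (7.19), SCIN (5.14), ADORA1 (4.41) and ARHGAP36 (-4.23). Without abemaciclib-resistant Y537S unit 1 they ended for CDK6 (0.89), CCNE2 (-1.22), TFF1 (1.79), SFTPA2 (6.3) and SCIN (3.74), and without its unit 2 for ESR1 (-0.73) and ARHGAP36 (-3.53). Without abemaciclib-resistant WT unit 2 they ended for ESR1 (-0.97) and SCIN (4.95), and without its unit 3 for ESR1 (-1). The lists that differed were E2F targets (-0.77), G2/M and mitosis (-0.61), cholesterol biosynthesis (-0.21), lysosome (0.34) and drug transport and metabolism (0.82). None was called with an estimated correlation (adjusted p = 0.494 to 0.69). The lysosome call ended without palbociclib-resistant WT unit 3 (0.23), abemaciclib-resistant WT unit 1 (0.31), palbociclib-resistant Y537S unit 1 (0.4) or abemaciclib-resistant Y537S unit 1 (0.3). Drug transport and metabolism was not called without palbociclib-resistant WT unit 2 or 3 (0.6, 0.88), abemaciclib-resistant WT unit 2 (0.8), palbociclib-resistant Y537S unit 1 (0.79) or abemaciclib-resistant Y537S unit 2 (0.55). Cholesterol biosynthesis was not called without palbociclib-resistant WT unit 2 (-0.22) or abemaciclib-resistant Y537S unit 2 (-0.16). G2/M moved to -0.38 without palbociclib-resistant WT unit 3, still called.

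Interferon-stimulated genes were lower in Y537S than in WT vehicle cells. A single odd unit is argued against: the list's median log2 level in the highest Y537S unit was below that of the lowest WT unit (-1.3). An effect of doxycycline of like size wherever it was given is argued against too, since in abemaciclib-resistant cells the same median was -0.26, a difference of 1.37 ± 0.31 (SE over units). The same values count as much against a Y537S receptor effect of like size, since doxycycline and Y537S coincide in all libraries. The abemaciclib-resistant cells were of batch 2 and had the list at 1.02 to 1.74 in both genotypes. In palbociclib-resistant cells the genotypes differed by -0.66 ± 0.41 (SE over units). Doxycycline and the Y537S receptor, either acting mainly in vehicle cells, cannot be told apart, because 0 WT libraries had doxycycline. Both therefore stay untested candidates, and induction of the receptor in vehicle cells is not shown by ESR1 counts or FPKM.

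Interferon-stimulated genes were higher in abemaciclib- than in palbociclib-resistant cells. Bias by GC content and transcript length as the whole cause is argued against: removing that trend moved the medians from 1.37 to 1.33 in WT and from 1.87 to 1.82 in Y537S cells. Drug and sequencing batch cannot be told apart, because 0 abemaciclib libraries were of batch 1. A batch shift of the same size in both genotypes could be the whole cause: the median difference of both rises was 0.48 with an interval over genes of 0.31 to 0.71, but over units it was 0.43 ± 0.47 (SE). The demand that it also pass 2 SE over units was added after the gene interval had been seen, and it moved that explanation from excluded to open.

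In resistant Y537S cells ESR1 was higher in the Cufflinks table, relative to its gene count, than in all other units. A difference between both tables that reaches genes in general is argued against: the ESR1 shift of 0.83 lay at percentile 100 of 1690 genes of like level, whose middle 95% ran from -0.01 to 0.08. A single odd unit is argued against in resistant cells, where the lowest Y537S unit was 1.79 times the highest other unit in FPKM per CPM. Construct reads that raise this ratio by a like factor in all Y537S units are argued against: in vehicle the means were 0.135 in Y537S and 0.136 in WT cells, and the log2 difference between genotypes was larger in resistant cells by 1.3 ± 0.19 (SE over units). A single odd unit in vehicle and construct reads of any smaller effect there stay open, since the gap of -0.0173 and the ratio of 0.874, which met conditions written beforehand for the former and against the latter, both rest on Y537S vehicle unit 2 (0.121). Construct reads or another transcript form of ESR1 in the resistant lines may be the cause: FPKM per CPM was 2.38 times that of the other units, and no table separates these, so both stay open.

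Splits of 3 against 3 units give 10 in all, too few for a share under 0.05. Every other split mixes units of both groups, so a real difference widens the spread within its groups and leaves few calls. The size of the gap to the other splits is therefore no further evidence against chance. The real split gave the most genes, 1 of 10, in each comparison: 172 against at most 0 in the others for Y537S in vehicle, 4982 against 0 for palbociclib resistance in WT cells, and 4553 against 1 for abemaciclib against palbociclib resistance in WT cells.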

How the results depend on the processing

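Chosen after the data were seen were leave-outs of units in the gene list tests and the removal of both deepest libraries or of the library with the highest mitochondrial share. The removals moved no count of changed genes by more than 1.36 times. In the same order throughout (Y537S against WT in palbociclib-resistant, vehicle and abemaciclib-resistant cells, palbociclib in WT and Y537S cells, abemaciclib against palbociclib in WT and Y537S cells, then the differences between genotypes in the response to palbociclib and to the inhibitors), single libraries as replicates gave 4464, 1858, 5893, 7606, 6571, 7298, 6420, 3304 and 4868 genes. Those counts take libraries of 1 unit as independent. The batch-corrected STAR table gave 340, 26, 6316, 1825, 1033, 708, 1810, 66 and 3206, of which 81.5%, 76.9%, 59.7%, 33.9%, 58.6%, 37.7%, 49.6%, 66.7% and 54.6% were higher. A log2 fold change of at least 1 besides left 704, 984, 1415, 1290, 1504, 1384, 393 and 843 for all but the vehicle comparison, since it drops smaller changes.

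Voom on single libraries with an estimated correlation (0.599) gave 485 genes for Y537S in vehicle and 1457 and 2560 for the differences in response. DESeq2's Wald test gave 457 in vehicle and 1278 for the palbociclib difference. Fitting only the groups compared gave 324, 1677 and 1539 for Y537S against WT, 2236 and 1014 for abemaciclib against palbociclib, and 107 for the inhibitor difference. In the single fit of all 6 groups the Y537S counts were 1580, 172 and 2894. Vehicle cells thus had the fewest genes in that fit and the most when fitted alone, so the counts do not rank the cell states. The single fit takes 1 spread per gene for all groups. Libraries of different units correlated at 0.991 to 0.9944 in vehicle and 0.9727 to 0.9803 in palbociclib-resistant WT cells. In Y537S cells these were 0.9832 to 0.9918 and 0.9869 to 0.9884. Where groups varied more than the shared spread, p-values of the single fit are too small, and where less, too large. The batch-corrected Cufflinks table gave 72 for vehicle, 864 and 754 for abemaciclib against palbociclib, and 1064 for the inhibitor difference. How far the shared spread sets the counts of the groups fitted alone was not tested, nor was the cause for the other settings named here. Gene list tests called with an estimated correlation were 0, against 72. Leaving out a unit gave 67 to 89, and of the 72 calls 49 stayed with each unit left out in turn and 23 were lost without at least 1.

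Leaving out a unit gave 477 to 1856, 47 to 90, 1111 to 3057, 3538 to 5176, 1642 to 3163, 3344 to 4723, 1662 to 3419, 166 to 1082 and 570 to 2569 genes in the order above. The lowest were without palbociclib-resistant Y537S unit 3 (477, 1642, 1662 and 166), WT vehicle unit 1 (47 and 3538), abemaciclib-resistant Y537S unit 1 (1111), abemaciclib-resistant WT unit 3 (3344) and palbociclib-resistant Y537S unit 1 (570). Where 1 unit stays in a group, it is assumed to vary like the other groups. The first number as a block gave 1446, 161, 2971, 5002, 3622, 4563, 3306, 575 and 1713, each within 1.5 times.

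ESR1 changed sign in Y537S against WT abemaciclib-resistant cells (Cufflinks 0.96, pseudocount 0.1 0.98, batch-corrected 0.89) and in palbociclib-resistant against vehicle Y537S cells (0.84, 0.86 and 0.86). In the gene counts the second of these changes was not called. Between the drugs in Y537S cells, batch-corrected values changed the sign of WISP2 (STAR 0.54, Cufflinks 0.43), FBN2 (STAR 0.31) and TGFB1 (Cufflinks 0.38). They left values near 0, a change lost and not reversed, for HIST1H2AC in WT cells (Cufflinks -0.05). The same was seen for FBN2 (Cufflinks 0) and B2M (STAR -0.01) in Y537S cells. The cause was not tested for these genes, and causes for ESR1 are weighed above. Of 403 named results, the side of the threshold and direction stayed in 403 with DESeq2 size factors, 399 with upper-quartile factors, 394 with voom, 390 without a filter, 380 with DESeq2, 377 in the Cufflinks table, 325 with only the groups compared, 292 in the batch-corrected Cufflinks and 261 in the batch-corrected STAR table.

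The median of all genes moved by more than 0.1 only with the Cufflinks table and a pseudocount of 0.1 (-0.142 for palbociclib in WT cells, 0.123 for the palbociclib difference). On simulated data of this depth and number of units, changes of 1.5-fold were often missed: 26.9% and 44.8% were recovered. Those data had the same spread in all groups and few changed genes, so recovery in the real comparisons may differ.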

Other observations

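The tests that leave out a unit were chosen after the data were seen. Lists of cholesterol synthesis, respiration, lysosomes and drug metabolism were also called. Cholesterol biosynthesis genes rose with palbociclib resistance in Y537S cells (6 of 24 up and none down, the same adjusted over the list alone; camera adjusted p = 0.0106; adjusted p = 0.494 with an estimated correlation), with LDLR, the LDL receptor, at 0.67 ± 0.11 (SE). They fell with abemaciclib against palbociclib in those cells (1 up and 11 down, the same adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.494 with an estimated correlation), ACAT2, which makes acetoacetyl-CoA, by 1.36 (SE 0.12) to 39.6 ± 3.34 CPM (SD, n = 2). In palbociclib-resistant cells the list was higher with Y537S, with 0 genes called over all genes and 0 adjusted over the list alone (median 0.18; camera adjusted p = 0.0381; adjusted p = 0.494 with an estimated correlation). Its responses differed between genotypes for palbociclib (1 higher, the same adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.494 with an estimated correlation). They differed for the inhibitors as well (3 lower, the same adjusted over the list alone; camera adjusted p = 0.0118; adjusted p = 0.494 with an estimated correlation). These last 3 calls were each lost without palbociclib-resistant WT unit 2.

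Nuclear genes of oxidative phosphorylation rose with palbociclib resistance in Y537S cells (8 of 50, the same adjusted over the list alone; camera adjusted p = 0.038; adjusted p = 0.735 with an estimated correlation) and none fell. They were lower with abemaciclib than with palbociclib in WT cells (9 down, the same adjusted over the list alone; camera adjusted p = 0.0321; adjusted p = 0.735 with an estimated correlation) and in Y537S cells (11 down, the same adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.692 with an estimated correlation). SDHA, a succinate dehydrogenase subunit, fell by 0.64 (SE 0.12) in WT cells, and UQCRH, a complex III subunit, by 0.69 (SE 0.12) in Y537S cells. The units overlapped in the first and second of these comparisons, and all 3 calls were lost without at least 1 unit. In WT cells the median moved from -0.14 to -0.03 without palbociclib-resistant unit 3. In vehicle the list's median was -0.16, with units that overlap, and with 0 genes called over all genes and 0 adjusted over the list alone (camera adjusted p = 6.55e-05; adjusted p = 0.682 with an estimated correlation). Mitochondrially encoded and histone genes, which vary with library composition, were higher with abemaciclib than with palbociclib, as was the mitochondrial share, in WT cells (6 of 13, the same adjusted over the list alone; camera adjusted p = 0.00275; adjusted p = 0.509 with an estimated correlation) and in Y537S cells (4, or 7 adjusted over the list alone; camera adjusted p = 0.0129; adjusted p = 0.621 with an estimated correlation). They were higher in Y537S vehicle cells (0 over all genes, 8 adjusted over the list alone; camera adjusted p = 0.00188; adjusted p = 0.494 with an estimated correlation), where library 2_2 had a mitochondrial share of 20.9%. Without Y537S vehicle unit 2 the median there moved from 0.5 to 0.15 and was not called. With palbociclib in WT cells 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0452; adjusted p = 0.69 with an estimated correlation). In vehicle and in this last comparison the units overlapped. That call was lost without vehicle unit 2 or palbociclib-resistant unit 1, and the one between drugs in Y537S cells without abemaciclib-resistant unit 2 (median 0.53, then 0.29). The palbociclib response differed by a median of -0.59, with 0 over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.494 with an estimated correlation). Without Y537S vehicle unit 2 the median was -0.33, still called.

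Lysosome genes rose with abemaciclib against palbociclib in Y537S cells (11 of 35 up and 2 down, or 14 and 2 adjusted over the list alone; camera adjusted p = 0.000175; adjusted p = 0.494 with an estimated correlation). GPNMB, a lysosomal glycoprotein, rose by 4.28 ± 0.53 (SE) to 364 ± 138 CPM (SD, n = 2). Between genotypes that response differed (6 higher and 2 lower, or 7 and 2 adjusted over the list alone; camera adjusted p = 0.035; adjusted p = 0.69 with an estimated correlation). That call was lost when any 1 of 4 units was left out, and without palbociclib-resistant WT unit 3 the median moved from 0.34 to 0.23. The unfolded protein and integrated stress response list rose too (9 of 27 up and 1 down, the same adjusted over the list alone; camera adjusted p = 0.00466; adjusted p = 0.494 with an estimated correlation), with DDIT4, an inhibitor of mTORC1, at 1.64 ± 0.2 (SE). Its median moved from 0.33 to 0.19 without abemaciclib-resistant unit 2, still called. Drug transport and metabolism genes fell with abemaciclib against palbociclib in WT cells (2 of 20 up and 11 down, or 2 and 12 adjusted over the list alone; camera adjusted p = 0.00202; adjusted p = 0.318 with an estimated correlation), CYP1A1, a drug-oxidizing enzyme, by 2.41 (SE 0.33). The genotypes differed in it (4 higher and 1 lower, or 5 and 1 adjusted over the list alone; camera adjusted p = 0.038; adjusted p = 0.494 with an estimated correlation), a call lost when any 1 of 5 units was left out. ABCG2, a drug efflux pump, was 48.9 ± 10.5 and 51.3 ± 13.3 CPM (SD, n = 2 and 2) in palbociclib- and abemaciclib-resistant Y537S cells. Those levels alone do not show its difference between genotypes. The call of that difference ended without palbociclib-resistant WT unit 3 (1.19) or abemaciclib-resistant WT unit 1 (1.12) or 3 (1.33). Without palbociclib-resistant Y537S unit 1 or 3 the difference was 1.09 or 1.52, and without abemaciclib-resistant Y537S unit 1 it was 1. In vehicle, inflammatory and NF-kB genes were lower in Y537S cells (median -0.28, with 0 over all genes and 1 of 17 lower adjusted over the list alone; camera adjusted p = 0.0358; adjusted p = 0.58 with an estimated correlation). That call was lost without WT unit 3 or Y537S unit 3.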
